A study of Mus musculus with 20 samples.

How the data were processed

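Liver RNA of male mice was measured by RNA-seq in 5 groups, per the labels: untreated wild type, and Fancd2 mutants that were untreated or given metformin, oxymetholone or both, with collection after 18 months of treatment. RNA was extracted with a column kit and libraries were made by a sequencing service, per the labels' protocols. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting program, the gene annotation, the strand setting and their versions are not given in the sources used here. The labels list 20 samples, of which 18 were used. Untreated mutant replicate 1 and metformin replicate 2 were not analysed here. Replicate numbers were given here in the order of the sample records, since the labels carry none.

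The authors deposited 1 table of 16115 genes. Its raw columns hold counts per gene and library, whole numbers without normalization, per the file headers. In every gene of the table at least 3 libraries reached 0.401 CPM, so the authors had removed genes with low counts. A second set of deposited columns holds a CPM signal, the counts relative to library size after scaling of each library by 1 factor, and these factors equal edgeR's TMM factors computed here from the counts (0.798 to 1.31). Another set of deposited columns holds log2 residuals, per the file headers. They differ from log2 CPM by a matrix of 3 components (53.6, 34.5 and 11.9% of the difference over 10638 genes). That is, 3 factors, known or estimated, had been removed, by a method not given in the sources used here. The authors also deposited log2 fold changes and p-values with adjusted p for 7 comparisons, by a test not given in the sources used here.

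All values reported here were computed from the deposited counts, except where the deposited results of the authors are named. The fit was edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (which removed no gene), a robust quasi-likelihood fit with 1 coefficient per group over all 18 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common dispersion was 0.181, a biological coefficient of variation of 0.426. Standard errors of log2 differences come from the same fit, and log2 CPM used a prior count of 2. Sets of genes were tested with camera (limma 3.58.1, preset correlation 0.01), again with a correlation estimated from the data, and with fry. Of 40 lists written before the data were examined, 36 kept at least 5 genes and were tested, and adjustment was over the 36.

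Total counts of 20.2 to 32.7 M per library set the depth. With reads thinned at random to 25% of each library, standard errors of the oxymetholone comparison rose by a median of 1.26 times among the weakest 25% of genes and 1.005 times among the strongest 25%. The procedure was tested on simulated counts with the real means, library sizes and groups, in which 200 genes with a mean of at least 1 CPM were changed. Recovery of weaker genes was therefore not measured. Counts were drawn independently for each gene and library, so neither correlation between genes nor outlying libraries were simulated, and real data can give more false calls. In the oxymetholone comparison edgeR recovered 24% of genes changed 2-fold, 78% at 4-fold, 94% at 8-fold and 98% at 16-fold, with 10 false calls of 157. In the genotype comparison it recovered 18, 78, 90 and 98% at these folds with 6 false calls of 148, in the metformin comparison 6, 72, 86 and 96% with 8 of 138, and in the combination comparison 14, 62, 88 and 98% with 7 of 138. DESeq2 made 33 false calls of 193 in the oxymetholone simulation and 44 of 193 in the combination simulation, against 10 and 7 false calls of edgeR in the same simulations.

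The groups, the 11 planned comparisons, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were Fancd2, the 10 with the largest rise and the 10 with the largest fall among those called that had a mean log2 CPM of at least 0, groups without overlap and a symbol not of a predicted gene, clone or pseudogene, the 5 with the smallest p where fewer than 5 passed, and up to 4 members by adjusted p of each list that was called or held a called gene. Of the list members the text gives those best known in liver, usually 1 or 2, and which lists it describes was chosen after the tests were seen. One result for a gene of that rule is not reported here. The main effects of oxymetholone and metformin (the mean of the effect with and without the other drug), the estimates that share no library, and the separation of 8 from 10 libraries were added after the data were examined.

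Alternatives planned were DESeq2 1.42.0, edgeR with DESeq2's size factors, no filter, a filter on a mean CPM of at least 1 (12803 genes), a fit of the compared groups alone, limma-voom with quality weights, and leaving out each library. Added after the data were examined were leaving out metformin replicate 3 together with combination replicate 3, the 3 factors recovered from the deposited residuals as covariates, 3 surrogate variables (sva 3.50.0), and a clock score. The clock score is the first principal component of the clock gene list.

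Drug effects were correlated across genes with the value expected from the shared untreated libraries, taken from 200 simulations without effects. A planned split of the untreated mutants into 2 and 2 was not possible with 3 libraries, so they were split 1 against 2 in all 6 ordered ways. The smaller part is a single library, which is assumed to vary like the others. Every comparison was also repeated on other splits of its libraries, all of them up to 100 and otherwise 100 drawn with a fixed seed.

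The available mouse reference annotation is of another build (GRCm38), so no coordinates are given, and it was used only for which genes neighbour each other. Gene names are those of the table, and 13 genes had none. Fancd2 was not analysed here. Counts are uncertain for genes with near-identical copies, such as members of the Mup, Cyp2a, Cyp3a, Serpina1, Saa, Gstm, Sult3a, Xlr4 and histone families, because the assignment of such reads is not given in the sources used here. Reads of overlapping or antisense genes cannot be told apart either, as no strand setting is given.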

Results

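RNA from the livers of male mice was sequenced in 5 groups at 18 months: untreated wild-type mice and Fancd2 mutant mice that were untreated or given metformin, oxymetholone or both drugs. Fancd2 encodes a protein of the Fanconi anaemia pathway, which repairs DNA crosslinks. Metformin is a glucose-lowering drug, and oxymetholone is an anabolic androgen used against marrow failure. Of the 20 labelled samples 18 libraries were analysed here. They were 4 wild-type libraries, 3 of untreated mutants, 3 of metformin mutants, 5 of oxymetholone mutants and 3 of mutants given the combination. Total counts per library were 23.7 to 29.2 M in wild type, 21.2 to 29.8 M in untreated mutants, 21.2 to 28.0 M with metformin, 21.8 to 32.7 M with oxymetholone and 20.2 to 32.4 M with the combination. Every library carried more RNA of Y-linked genes than of Xist (18 of 18), as labelled for males. Nothing in the labels rules on whether each library came from a separate animal, and libraries of a group differed far beyond counting error (chi-square per degree of freedom of at least 73.5 for each pair).

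Fancd2 itself was not analysed here, so the mutation was not checked against the labels. Expression values below are CPM, counts relative to the TMM-scaled library size, given as mean ± SD over the libraries of a group. Log2 differences are given ± SE from edgeR, and adjusted p is edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16115 genes unless another tool is named. List tests are camera's, with a preset correlation of 0.01 between genes and again with an estimated one. Libraries of metformin replicate 3 and combination replicate 3 lay farthest from the rest, with a median correlation with other libraries of 0.926 and 0.916.

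The question of the first comparison was what loss of Fancd2 changes in the untreated liver. Ribosomal protein genes as a list lay higher in the 3 untreated mutants than in the 4 wild types (43 of 44 genes higher, median log2 difference 0.55, camera adjusted p = 6.8e-17), with adjusted p = 0.853 with an estimated correlation. Acute-phase genes, which the liver makes in inflammation, also lay higher (24 of 26, median 0.84, camera adjusted p = 2.3e-05), with adjusted p = 0.972 with an estimated correlation. Pericentral genes, expressed around the central vein, lay lower (20 of 22, median −0.41, camera adjusted p = 4.12e-05), with adjusted p = 0.853 with an estimated correlation. Among them were Glul, the glutamine synthetase of the cells next to the vein (734 ± 224 CPM in wild type and 357 ± 75.5 CPM in mutants, log2 difference −1.04 ± 0.33, edgeR adjusted p = 0.973), and the Wnt feedback gene Nkd1 (−1.16 ± 0.45, edgeR adjusted p = 0.973). Target genes of the xenobiotic receptors PXR and CAR lay lower in 24 of 29 genes (median −0.47, camera adjusted p = 0.000263), with adjusted p = 0.853 with an estimated correlation. The transporter Abcc2 was among them (−1.11 ± 0.33, edgeR adjusted p = 0.973). Lipogenesis genes (19 of 20 lower, median −0.39, camera adjusted p = 0.000263) and gluconeogenesis genes (16 of 20 lower, median −0.35, camera adjusted p = 0.00268) each had adjusted p = 0.884 with an estimated correlation. Pck1 and G6pc, which encode 2 enzymes of glucose release, had log2 differences of −1.55 ± 0.60 and −1.38 ± 0.51 (edgeR adjusted p = 0.973 for both). The Fanconi anaemia pathway list (28 genes, median −0.06, camera adjusted p = 0.963) and the list of p53 targets (32 genes, median 0.03, camera adjusted p = 0.945) did not pass.

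No single gene passed in that comparison. EdgeR called 0 of 16115 genes, with 416 at an unadjusted p under 0.05 where chance gives 806, and DESeq2 and limma-voom also called 0. The unadjusted p values depended on the tool, with 559 genes under 0.05 by DESeq2 and 4080 by limma-voom. In none of these 8 lists was a gene called over all genes or adjusted over the list alone. Mitochondrial genes held 2.04 to 2.60% of counts in the untreated mutants and 2.95 to 3.85% in wild type, without overlap. The treated mutants held 3.25 to 3.89% with metformin, 1.77 to 8.19% with oxymetholone and 1.54 to 3.29% with the combination. The difference between the libraries thus goes with these 2 groups and not with the genotype over all mutants. The smallest p values belonged to the long noncoding gene Gm4468 (−2.65 ± 0.59), the histone gene H4f16 (2.45 ± 0.58) and Tsku, which encodes a secreted Wnt and TGF-beta modulator (65.9 ± 27.2 CPM in wild type and 14.0 ± 4.56 CPM in mutants, −2.24 ± 0.56), each with edgeR adjusted p = 0.973. Mup22, a major urinary protein gene (4.91 ± 1.29, edgeR adjusted p = 0.973), rested on untreated mutant replicate 3 with 277 CPM. The acute-phase gene Saa3 ranged from 17.7 to 436 CPM over the 3 mutants (2.84 ± 1.08, edgeR adjusted p = 0.973). Camera called 12 lists here, but 2 without untreated mutant replicate 2, and 23 of the 35 splits of the 7 libraries called at least as many. Without that library the acute-phase, pericentral, xenobiotic receptor, lipogenesis and gluconeogenesis lists were among those lost (camera adjusted p = 0.264 to 0.319), and the last also without wild-type replicate 3 (0.0604).

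The metformin comparison asked what the drug changes in the mutant liver. Cholesterol synthesis genes lay lower in the 3 metformin mutants than in the 3 untreated mutants (23 of 25, median log2 difference −0.68, camera adjusted p = 2.86e-09). Within that list were the mevalonate pathway enzyme gene Pmvk (−1.42 ± 0.50, edgeR adjusted p = 0.655) and Cyp51, which encodes lanosterol demethylase (−0.99 ± 0.41, edgeR adjusted p = 0.785). Acute-phase genes lay lower in 25 of 26 (median −1.37, camera adjusted p = 5.52e-11). They were led by the metallothionein gene Mt2 (−5.02 ± 1.68, edgeR adjusted p = 0.607). Genes of respiratory complex I, which metformin inhibits, lay lower in 34 of 36 (median −0.33, camera adjusted p = 2.02e-05). Gluconeogenesis genes did not pass (20 genes, median 0.04 against a camera direction of lower, adjusted p = 0.698). Proliferation genes lay higher in 33 of 33 (median 1.3, camera adjusted p = 3.33e-08), a call kept without any 1 library. Their log2 score relative to wild type was 1.84 in metformin replicate 4, 0.568 in replicate 3 and −0.0493 in replicate 1. They included Top2a (1.96 ± 0.85, edgeR adjusted p = 0.825) and Cenpf (2.91 ± 1.31, edgeR adjusted p = 0.849). Top2a had 5.82 CPM in replicate 4, at most 1.92 in the group's others. The list of male-biased liver genes lay higher in 22 of 26 (median 0.65, camera adjusted p = 0.00217). Selenbp2 was its first member (3.90 ± 1.11, edgeR adjusted p = 0.579). Neutrophil genes lay lower in 13 of 16 (median −1.94, camera adjusted p = 3.1e-05). With an estimated correlation, each list given here as passing had adjusted p = 0.707.

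Bile duct cell genes lay higher with metformin in 15 of 17 (median 2.57, camera adjusted p = 0.000289, and 0.707 with an estimated correlation). Most of that difference sat in metformin replicate 3. Keratin gene Krt19 reached 237 CPM there, against 0.684 CPM in the lowest metformin library and 2.06 ± 1.47 CPM in untreated mutants (5.25 ± 1.67). The mucin gene Muc1 reached 155 CPM in replicate 3 (6.45 ± 1.67), while the imprinted fetal gene H19 reached 283 CPM in metformin replicate 4 and 10.2 CPM in replicate 3 (6.50 ± 1.91, edgeR adjusted p = 0.579 for all 3). Fibrosis and stellate cell genes lay higher in 26 of 29 (median 1.17, camera adjusted p = 7.31e-05, and 0.707 with an estimated correlation). The smooth muscle actin gene Acta2 (4.31 ± 1.45, edgeR adjusted p = 0.607) reversed its sign without that library. EdgeR called 0 genes for metformin (914 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 11. Of these lists only the bile duct list had genes called when adjusted over the list alone (5 of 17 higher). Tnnt2, a troponin gene (3.76 ± 0.86), and Parm1 (3.79 ± 0.85) had the smallest p values, each with edgeR adjusted p = 0.579. In metformin replicate 3 they had 7.50 and 9.48 CPM, at most 0.892 and 1.22 elsewhere. Without metformin replicate 3 the bile duct list (camera adjusted p = 0.424), the fibrosis list (0.132) and complex I (0.29) lost their calls, and complex I also without untreated mutant replicate 3 (0.0732). The neutrophil list lost its call without metformin replicate 1 (0.0688) and the male-biased list without that library or untreated mutant replicate 2 (0.102 and 0.0542).

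The oxymetholone comparison asked what the androgen changes in the mutant liver. Paqr8, which encodes a membrane progestin receptor, rose from 1.43 ± 0.323 CPM in 3 untreated mutants to 22.8 ± 6.81 CPM in 5 oxymetholone mutants (log2 difference 4.0 ± 0.39, edgeR adjusted p = 0.000169). Wif1, which encodes a secreted Wnt inhibitor, rose from 0.711 ± 0.438 CPM to 31.5 ± 13.3 CPM (5.49 ± 0.60, edgeR adjusted p = 0.00033). Lncbate1, a long noncoding RNA gene known from brown fat, rose from 0.231 ± 0.182 CPM to 16 ± 7.80 CPM (6.04 ± 0.78, edgeR adjusted p = 0.00271). Rab38, a small GTPase of lysosome-related organelles, rose from 2.91 ± 0.762 CPM to 14.7 ± 2.33 CPM (2.32 ± 0.40, edgeR adjusted p = 0.0443). Tmem62 fell from 20.3 ± 4.24 CPM to 3.54 ± 1.01 CPM (−2.52 ± 0.26, edgeR adjusted p = 0.000169). Ubr1, which encodes a ubiquitin ligase of the N-degron pathway, fell from 15.9 ± 3.35 CPM to 4.22 ± 1.25 CPM (−1.92 ± 0.26, edgeR adjusted p = 0.00407), and it neighbours Tmem62 on the chromosome. Over all 16115 genes, 557 had every oxymetholone library on one side of every untreated mutant library, and chance gives this for 3.57% of genes over both directions, so such separation was no more frequent than by chance.

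**Figure D1:**
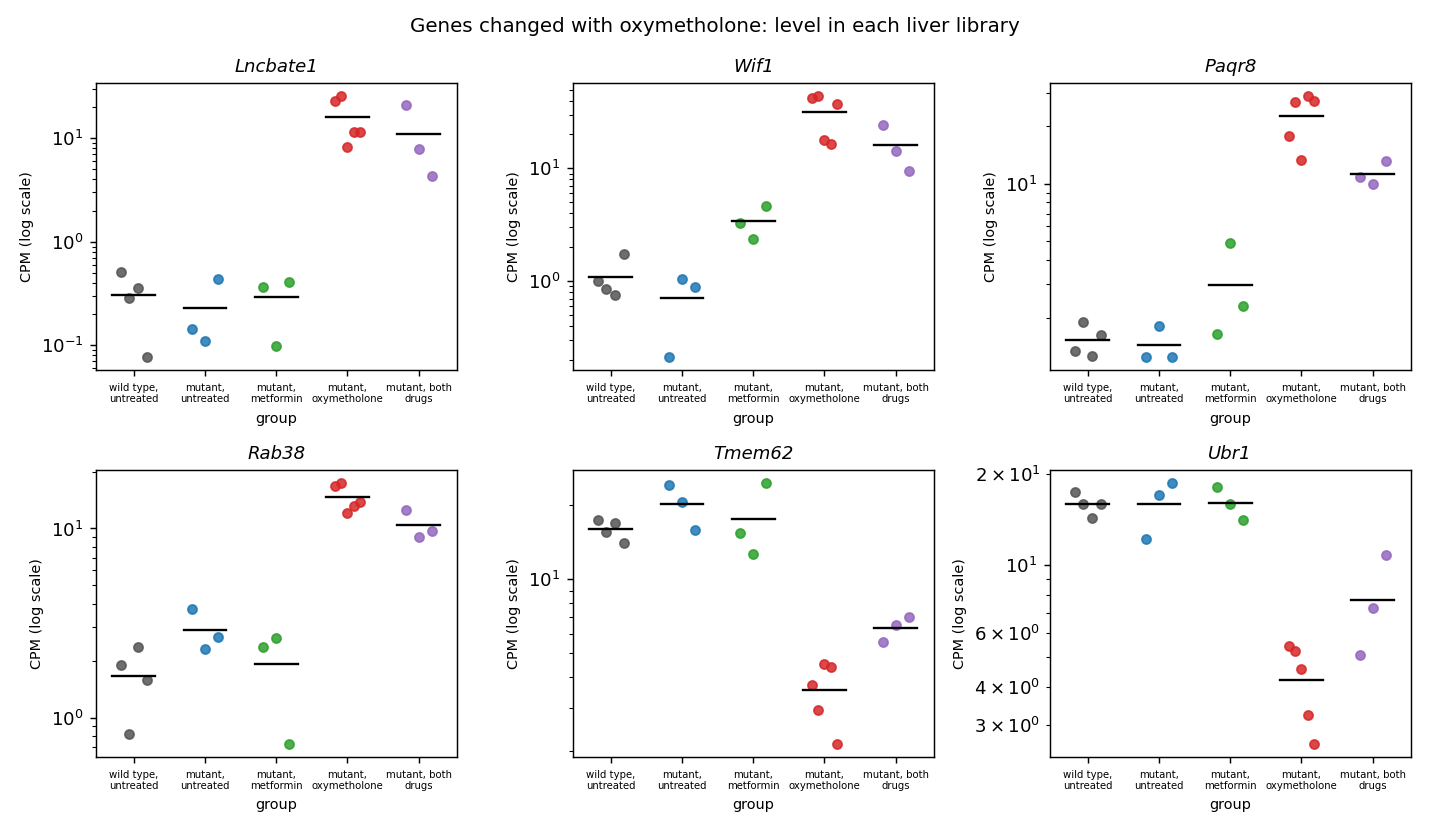
CPM on a log axis of Lncbate1, Wif1, Paqr8, Rab38, Tmem62 and Ubr1 in the 5 groups, with a point per library and a line at the group mean. Paqr8 lay at 13.4 to 28.9 CPM with oxymetholone and at 9.94 to 13.1 CPM with the combination, against at most 4.92 CPM in any other library.

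The seventh gene called was Mcmdc2, a gene of meiotic recombination, which fell (−6.40 ± 1.03, edgeR adjusted p = 0.0278). It lay outside the rule for named genes because of its low level, and was chosen after its values were seen. In all, edgeR called 7 genes for oxymetholone, 4 higher and 3 lower, with 773 at an unadjusted p under 0.05. DESeq2 called 78 and limma-voom 14, and both kept the 7. Leaving out any 1 of the 8 libraries ended the call of Rab38 (edgeR adjusted p = 0.0517 to 0.355), any 1 but untreated mutant replicate 2 that of Mcmdc2 (0.0674 to 0.146), and untreated mutant replicate 4 that of Ubr1 (0.0519), whereas Paqr8, Wif1, Lncbate1 and Tmem62 passed each time. The deposited results of the authors call 47 genes for this comparison (25 higher and 22 lower), among them the 7, and the other 40 include the interferon-induced gene Usp18 (3.32 ± 1.21 CPM in untreated mutants and 18.0 ± 10.4 CPM with oxymetholone, 2.43 ± 0.73, edgeR adjusted p = 0.616). All 47 had the same sign in edgeR, and 41 had an unadjusted edgeR p under 0.05. Of the 56 splits of the 8 libraries, the real one included, 2 called at least as many genes.

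Camera with the preset correlation called 15 lists for oxymetholone mutants against untreated mutants, and with an estimated one it called none. The integrated stress response list, the genes that ATF4 and CHOP induce, lay higher in 17 of 19 genes (median log2 difference 0.61, camera adjusted p = 0.00108), with adjusted p = 0.0517 with an estimated correlation. Its members included Ddit3, which encodes CHOP (0.89 ± 0.29, edgeR adjusted p = 0.714), Atf3 (2.11 ± 0.78, edgeR adjusted p = 0.877) and Nupr1 (1.5 ± 0.59, edgeR adjusted p = 0.877). Interferon response genes lay higher in 27 of 28 (median 0.86, camera adjusted p = 1.16e-06), with adjusted p = 0.857 with an estimated correlation. Oasl1 (3.20 ± 1.12, edgeR adjusted p = 0.877) followed Usp18. Clock genes lay higher in 16 of 22 (median 1.01, camera adjusted p = 2.73e-05), with adjusted p = 0.529 with an estimated correlation. They were led by Usp2 (4.04 ± 0.96, edgeR adjusted p = 0.299) and Bhlhe40 (1.18 ± 0.31, edgeR adjusted p = 0.401). Proliferation genes lay higher in 32 of 33 (median 1.03, camera adjusted p = 3.57e-07), and cholesterol synthesis genes lay lower in 22 of 25 (median −0.42, camera adjusted p = 9.23e-06), both with adjusted p = 0.857 with an estimated correlation. NRF2 targets lay higher in 24 of 28 (median 0.64, camera adjusted p = 0.000726), with adjusted p = 0.857 with an estimated correlation. Gstm3 was among them (3.0 ± 1.0, edgeR adjusted p = 0.784).

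Steroid receptor responses were of interest because the drug is an androgen. That list lay higher in 18 of 24 genes (median 0.51, camera adjusted p = 0.00151), with adjusted p = 0.529 with an estimated correlation. It held the glucocorticoid and androgen target Fkbp5 (2.44 ± 0.80, edgeR adjusted p = 0.727) and Cebpd (1.40 ± 0.43, edgeR adjusted p = 0.659). Male-biased liver genes lay higher in 21 of 26 (median 0.48, camera adjusted p = 0.00654), with adjusted p = 0.89 with an estimated correlation. They were led by Selenbp2 (4.07 ± 1.08, edgeR adjusted p = 0.441) and Mup20 (2.85 ± 0.86, edgeR adjusted p = 0.648). Female-biased genes did not pass (28 genes, median 0.23 against a camera direction of lower, adjusted p = 0.944), nor did iron and hepcidin genes (22 genes, median −0.01 against a direction of higher, adjusted p = 0.838), growth hormone and IGF genes (17 genes, median −0.05, adjusted p = 0.884), p53 targets (32 genes, median 0.07, adjusted p = 0.838) or the Fanconi anaemia pathway (28 genes, median 0.09, adjusted p = 0.944). No gene of these 13 lists was called over all genes. Adjusted over the list alone, 7 clock genes (6 higher, 1 lower), 3 male-biased genes (higher), 4 female-biased genes (2 each way) and 1 p53 target (lower) passed. Camera called 15 lists, but 8 without untreated mutant replicate 2, and 19 of the 56 splits of the 8 libraries called at least as many. Male-biased genes lost their call without untreated mutant replicate 2 or oxymetholone replicate 1 or 3 (camera adjusted p = 0.0721 to 0.109), steroid responses without untreated mutant replicate 2 (0.0782) and NRF2 targets without oxymetholone replicate 5 (0.129).

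The combination comparison asked the same of both drugs together. Wif1 rose to 16.1 ± 7.58 CPM in the 3 combination mutants (log2 difference from untreated mutants 4.52 ± 0.59, edgeR adjusted p = 0.00639). Paqr8 rose to 11.3 ± 1.64 CPM (2.99 ± 0.39, edgeR adjusted p = 0.00639), and Lncbate1 rose to 11.1 ± 8.86 CPM (5.51 ± 0.79, edgeR adjusted p = 0.0131). These were the only calls of edgeR (3 higher, 0 lower, with 880 at an unadjusted p under 0.05), while DESeq2 called 43 and limma-voom 16. Fitted to the 2 compared groups alone, edgeR kept 0 of the 3 calls and made no other (612 at an unadjusted p under 0.05). Over all 16115 genes, 1396 had the 2 groups without overlap, no more than the 10% of genes that chance gives. Without untreated mutant replicate 2 or 4 edgeR called none of the 3 (edgeR adjusted p = 0.0687 to 0.228), and without replicate 3 it called Wif1 and Paqr8 alone. The other oxymetholone genes had the same sign without passing: Rab38 (1.83 ± 0.41, edgeR adjusted p = 0.419), Tmem62 (−1.67 ± 0.29, edgeR adjusted p = 0.12) and Ubr1 (−1.04 ± 0.30, edgeR adjusted p = 0.699).

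Cholesterol synthesis genes lay lower with the combination in 25 of 25 genes (median −1.01, camera adjusted p = 7.5e-17), with adjusted p = 0.493 with an estimated correlation. Sc5d, which encodes lathosterol oxidase, measured 514 ± 168 CPM in untreated mutants and 192 ± 39.0 CPM with both drugs (−1.42 ± 0.39, edgeR adjusted p = 0.648), and Msmo1 (−1.40 ± 0.39, edgeR adjusted p = 0.67) and Dhcr7 (−1.45 ± 0.45, edgeR adjusted p = 0.776) were close to it. Targets of the fatty acid receptor PPAR-alpha lay higher in 30 of 32 (median 0.57, camera adjusted p = 1.54e-05, and 0.762 with an estimated correlation). They included Vnn1 and the lipid droplet gene Cidec (1.76 ± 0.44 and 1.60 ± 0.43, edgeR adjusted p = 0.509 and 0.633). The list scored 0.65, 0.728 and −0.352 in combination replicates 1 to 3 and −0.379 to 0.165 in untreated mutants. The integrated stress response list lay higher in 14 of 19 (median 0.31, camera adjusted p = 0.00252, and 0.105 with an estimated correlation). It held Ddit3, Psat1 and Phgdh (1.28 ± 0.32, 2.12 ± 0.60 and 2.09 ± 0.63, edgeR adjusted p = 0.509, 0.688 and 0.776). The last 2 had 23.3 and 10.8 CPM in combination replicate 3, at most 4.28 and 2.14 in the group's others. Interferon response genes lay higher in 25 of 28 (median 0.81, camera adjusted p = 4.11e-05), proliferation genes in 31 of 33 (median 1.43, camera adjusted p = 1.09e-06) and coagulation and complement genes lower in 34 of 42 (median −0.38, camera adjusted p = 7.42e-07), each with adjusted p = 0.762 with an estimated correlation. Female-biased liver genes lay higher in 21 of 28 (median 1.11, camera adjusted p = 0.0185, and 0.782 with an estimated correlation). Cyp2a4, a steroid hydroxylase gene, measured 22.7 ± 9.63 CPM in untreated mutants and 549 ± 351 CPM with both drugs (4.59 ± 1.09, edgeR adjusted p = 0.489). Adjusted over the list alone, 4 cholesterol synthesis genes (lower), 2 PPAR-alpha targets, 4 stress response genes (higher) and 6 female-biased genes (5 higher, 1 lower) passed. Without combination replicate 3 the interferon, proliferation, coagulation and female-biased lists lost their calls (camera adjusted p = 0.531 to 0.904) and the last changed direction, and it lost its call also without untreated mutant replicate 2 (0.348). Combination replicate 3 scored 2.09 for the interferon list, 2.3 for proliferation, 3.0 for bile duct genes, 2.09 for fibrosis, 2.1 for T and NK cell genes and 3.06 for liver tumour markers, at most 0.639 in the group's others.

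Whether adding metformin changed the response to oxymetholone was tested by the difference between combination and oxymetholone mutants. Cholesterol synthesis genes lay lower with the combination in 25 of 25 genes (median log2 difference −0.58, camera adjusted p = 1.19e-06), with adjusted p = 0.981 with an estimated correlation. They were led by Dhcr7 (−1.03 ± 0.41, edgeR adjusted p = 0.956). Periportal genes lay lower in 15 of 20 (median −0.50, camera adjusted p = 1.19e-06), with adjusted p = 0.981 with an estimated correlation. They were led by the serine dehydratase gene Sds (−1.33 ± 0.45, edgeR adjusted p = 0.956). Male-biased genes lay lower in 17 of 26 (median −0.47, camera adjusted p = 0.000337) and female-biased genes lay higher in 23 of 28 (median 1.34, camera adjusted p = 0.0034), both with adjusted p = 0.981 with an estimated correlation. Cyp3a16, a female-biased cytochrome gene, reached 46.1 CPM in combination replicate 3 and 0.051 CPM in the lowest library of that group (5.15 ± 1.3, edgeR adjusted p = 0.956). EdgeR called 0 genes, with 461 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 1. Of the female-biased genes 4 passed when adjusted over the list alone (higher), against 0 over all genes. Zfp658 (1.76 ± 0.34) and Acmsd, which encodes an enzyme of tryptophan breakdown (−1.85 ± 0.37), had the smallest p values (edgeR adjusted p = 0.885 for both). Without combination replicate 3 the periportal (camera adjusted p = 0.278), male-biased (0.118, with the direction reversed) and female-biased (0.927) lists lost their calls, the last also without oxymetholone replicate 1 (0.0582).

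Adding oxymetholone to metformin was tested by the difference between combination and metformin mutants. The integrated stress response list lay higher with the combination in 16 of 19 (median log2 difference 0.48, camera adjusted p = 0.000653). It passed also with an estimated correlation (adjusted p = 0.0305) and not with fry (0.116). Ddit3 measured 3.74 ± 1.16 CPM with metformin and 8.03 ± 1.27 CPM with both drugs (1.10 ± 0.31, edgeR adjusted p = 0.999). Psat1 (2.11 ± 0.60, edgeR adjusted p = 0.999) had 23.3 CPM in combination replicate 3, at most 4.28 in the group's others. Interferon response genes lay higher in 27 of 28 (median 0.90, camera adjusted p = 9.03e-08, and 0.912 with an estimated correlation). Female-biased genes lay higher in 23 of 28 (median 1.46, camera adjusted p = 6.34e-06, and 0.716 with an estimated correlation). Bile duct genes lay lower in 12 of 17 (median −0.55, camera adjusted p = 0.024, and 0.912 with an estimated correlation). Lncbate1 came closest among single genes (0.291 ± 0.167 CPM with metformin, 5.24 ± 0.77, edgeR adjusted p = 0.0555), before Rab38 (2.45 ± 0.42, edgeR adjusted p = 0.128) and Paqr8 (1.93 ± 0.37, edgeR adjusted p = 0.306). EdgeR called 0 genes, with 552 at an unadjusted p under 0.05, DESeq2 called 10 and limma-voom 3. Of their members, 5 female-biased genes and 2 stress response genes passed when adjusted over the list alone (all higher), against 0 over all genes. The stress response list lost its call without metformin replicate 1 (camera adjusted p = 0.0518), the interferon list without that library or combination replicate 3 (0.053 and 0.167), the female-biased list without combination replicate 3 (0.0539), and the bile duct list without metformin replicate 3 or 4 or combination replicate 1 or 2 (0.0929 to 0.574).

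The interaction of the drugs asked whether metformin acted differently with and without oxymetholone. Male-biased genes had a negative interaction in 25 of 26 (median −1.18, camera adjusted p = 4.09e-06), with adjusted p = 0.925 with an estimated correlation. They were led by Selenbp2 (−6.70 ± 1.49, edgeR adjusted p = 0.863), which measured 9.09 ± 3.82 CPM untreated, 136 ± 130 CPM with metformin, 152 ± 180 CPM with oxymetholone and 21.9 ± 13.6 CPM with both. Female-biased genes had a positive one in 22 of 28 (median 0.88, camera adjusted p = 0.00285), with adjusted p = 0.925 with an estimated correlation, and the transporter gene Slc22a26 was among them (6.11 ± 1.26, edgeR adjusted p = 0.863). Ribosomal protein genes (42 of 44 positive, median 0.50, camera adjusted p = 1.15e-09) and acute-phase genes (23 of 26 positive, median 0.70, camera adjusted p = 0.000116) also had a positive interaction, both with adjusted p = 0.925 with an estimated correlation. Of the genes called for oxymetholone, Wif1 (−3.28 ± 0.72), Paqr8 (−2.06 ± 0.50), Tmem62 (1.06 ± 0.39) and Lncbate1 (−0.80 ± 0.99) had interaction estimates that did not pass (edgeR adjusted p = 0.863 for the first 3 and 0.869 for Lncbate1). EdgeR called 0 genes, with 483 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 3. Adjusted over the list alone, 1 male-biased gene (negative) and 4 female-biased genes (positive) passed, against 0 over all genes. Without combination replicate 3 the male-biased (camera adjusted p = 0.187) and female-biased (0.261) lists lost their calls, as did the acute-phase list without untreated mutant replicate 2 (0.164).

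A direct comparison of the single drugs set 5 oxymetholone against 3 metformin mutants. Lncbate1 was higher with oxymetholone (5.77 ± 0.77, edgeR adjusted p = 0.00479), as were Wif1 (3.45 ± 1.15 CPM with metformin, 3.19 ± 0.51, edgeR adjusted p = 0.0209), Rab38 (2.94 ± 0.41, edgeR adjusted p = 0.00551) and Paqr8 (2.94 ± 0.37, edgeR adjusted p = 0.00315). Tmem62 (−2.32 ± 0.25, edgeR adjusted p = 0.00108) and Ubr1 (−1.93 ± 0.26, edgeR adjusted p = 0.00479) were lower. Adgrg7, an adhesion receptor gene of the gut, was also called lower (−12.52 ± 2.04, edgeR adjusted p = 0.021), with 214 CPM in metformin replicate 3 and at most 0.526 CPM in the other metformin libraries. The integrated stress response list lay higher with oxymetholone in 17 of 19 (median 0.60, camera adjusted p = 6.44e-05). It passed also at adjusted p = 0.0138 with an estimated correlation and not with fry (adjusted p = 0.119), and Eif4ebp1 (0.72 ± 0.21, edgeR adjusted p = 0.286) and Cebpb (1.06 ± 0.41, edgeR adjusted p = 0.678) were members. Steroid receptor responses lay higher in 22 of 24 (median 0.64, camera adjusted p = 1.11e-06), with adjusted p = 0.0943 with an estimated correlation. Interferon response genes (27 of 28 higher, median 0.64, camera adjusted p = 1.12e-11), acute-phase genes (22 of 26 higher, median 0.97, camera adjusted p = 1.54e-05) and bile duct genes (16 of 17 lower, median −3.01, camera adjusted p = 6.52e-07) each had adjusted p = 0.732 with an estimated correlation. EdgeR called 9 genes (6 higher and 3 lower, 880 at an unadjusted p under 0.05), DESeq2 107 (26 higher and 81 lower) and limma-voom 6 (4 higher and 2 lower). Fitted to the 2 compared groups alone, edgeR kept 0 of the 9 calls and made no other (605 at an unadjusted p under 0.05). Without metformin replicate 1 edgeR called 153 (6 higher and 147 lower), without replicate 4 it called 57 (8 higher and 49 lower) and without replicate 3 it called 5 (3 higher and 2 lower). Wif1 lost its call without metformin replicate 3 or oxymetholone replicate 1, 2 or 5 (edgeR adjusted p = 0.0535 to 0.208), and Adgrg7 without metformin replicate 3 or any 1 oxymetholone library (0.114 to 0.688). The bile duct list lost its call without metformin replicate 3 (camera adjusted p = 0.183) and the acute-phase list without oxymetholone replicate 4 (0.178). Of the bile duct genes 7 passed when adjusted over the list alone (lower), against 0 over all genes.

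Mutants given oxymetholone were also set against wild-type mice, which share no library with the untreated mutants. The oxymetholone libraries are the same as before, so a repeated call is not a replication. Genotype and drug both differ between these groups, so genes called only here cannot be assigned to either. Paqr8 (1.52 ± 0.288 CPM in 4 wild types, log2 difference 3.90 ± 0.34, edgeR adjusted p = 4.68e-05), Wif1 (4.85 ± 0.50, edgeR adjusted p = 0.000241) and Lncbate1 (5.70 ± 0.67, edgeR adjusted p = 0.00057) were higher, and Tmem62 (−2.18 ± 0.24, edgeR adjusted p = 0.000413) and Ubr1 (−1.91 ± 0.25, edgeR adjusted p = 0.00173) were lower. Cyp2a4 was higher (9.37 ± 8.05 CPM in wild type and 624 ± 586 CPM with oxymetholone, 6.06 ± 1.0, edgeR adjusted p = 0.0195), although it shares much of its sequence with other Cyp2a genes and its counts are uncertain for that reason. Slco4c1, a transporter gene (5.92 ± 1.02, edgeR adjusted p = 0.0263), and the heme-binding protein gene Hebp2 (3.94 ± 0.71, edgeR adjusted p = 0.0358) were higher. The desmoglein gene Dsg1c (−2.38 ± 0.40, edgeR adjusted p = 0.024), Tenm3 (−2.07 ± 0.30, edgeR adjusted p = 0.00647) and Cyp2c39 (−1.92 ± 0.32, edgeR adjusted p = 0.0195) were lower. EdgeR called 16 genes (11 higher, 5 lower, 727 at an unadjusted p under 0.05), DESeq2 89 and limma-voom 43, and no other of the 100 splits drawn gave more than 1. Calls fell to 9 without wild-type replicate 4 and 10 without replicate 1. Hebp2 lost its call without any 1 library but oxymetholone replicate 3 (edgeR adjusted p = 0.0541 to 0.204), Slco4c1 without any 1 but oxymetholone replicates 3 and 4 (0.0539 to 0.179), Dsg1c without any 1 but wild-type replicate 1 and oxymetholone replicate 3 (0.0515 to 0.115), and Cyp2c39 without wild-type replicate 3 or 4 or oxymetholone replicate 1, 2, 3 or 4 (0.0577 to 0.0915). Cyp2a4 lost it without wild-type replicate 1, 3 or 4 (0.11 to 0.145). Genes of the integrated stress response lay higher in 15 of 19 (median 0.69, camera adjusted p = 0.000334). It passed also at adjusted p = 0.0223 with an estimated correlation and not with fry (adjusted p = 0.0653).

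Other lists of that comparison lost their call with the estimated correlation. Interferon response genes (28 of 28 higher, median 0.85, camera adjusted p = 1.02e-07), proliferation genes (30 of 33 higher, median 0.65, camera adjusted p = 9.88e-07) and cholesterol synthesis genes (23 of 25 lower, median −0.46, camera adjusted p = 2.85e-09) each had adjusted p = 0.929 with an estimated correlation. Cholesterol scores were −1.31 and −1.38 in oxymetholone replicates 2 and 5, and −0.226 to 0.00398 in the other replicates. Female-biased genes did not pass (28 genes, median −0.07 against a mean of 0.13, camera adjusted p = 0.361), though Cyp2a4 among them was called over all genes, and 3 were called adjusted over the list alone (1 higher, 2 lower). So was 1 stress response gene (higher).

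Combination mutants were set against wild type in the same way. Paqr8 (2.89 ± 0.35, edgeR adjusted p = 0.00428), Lncbate1 (5.17 ± 0.68, edgeR adjusted p = 0.00444), Wif1 (3.88 ± 0.50, edgeR adjusted p = 0.00444) and Rab38 (2.64 ± 0.39, edgeR adjusted p = 0.0122) were higher, and these were the 4 genes that edgeR called (4 higher, 0 lower, 1110 at an unadjusted p under 0.05), with 70 called by DESeq2 and 35 by limma-voom. Fitted to the 2 compared groups alone, edgeR kept 1 of the 4 calls and made no other (1464 at an unadjusted p under 0.05). Cholesterol synthesis genes lay lower in 25 of 25 (median −1.0, camera adjusted p = 3.76e-17) and periportal genes in 17 of 20 (median −0.70, camera adjusted p = 1.05e-06), both with adjusted p = 0.471 with an estimated correlation. Female-biased genes (22 of 28 higher, median 1.14, camera adjusted p = 0.00164) and lipogenesis genes (18 of 20 lower, median −0.47, camera adjusted p = 4.8e-05) both had adjusted p = 0.663 with an estimated correlation. The integrated stress response list lay higher in 12 of 19 (median 0.41, camera adjusted p = 0.00667), with adjusted p = 0.228 with an estimated correlation. Adjusted over the list alone, 8 cholesterol synthesis genes (lower), 9 female-biased genes (8 higher, 1 lower) and 4 stress response genes (higher) passed, against 0 over all genes. No other split of the 7 libraries called a gene. Rab38 lost its call without wild-type replicate 1 or 4 or combination replicate 1 (edgeR adjusted p = 0.0544 to 0.0737), and the female-biased list without combination replicate 3 (camera adjusted p = 0.448).

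For metformin mutants against wild type camera called 17 lists with the preset correlation and none with an estimated one. Neutrophil genes lay lower in 16 of 16 (median −3.11, camera adjusted p = 1.33e-09) and cholesterol synthesis genes in 25 of 25 (median −0.66, camera adjusted p = 1.1e-15), both with adjusted p = 0.403 with an estimated correlation. The neutrophil granule gene Camp (−9.07 ± 2.60, edgeR adjusted p = 0.427) had 58.2 CPM in the highest wild-type library and 0.285 CPM in the lowest. Liver tumour markers (20 of 21 higher, median 1.66, camera adjusted p = 2.28e-08) had adjusted p = 0.403 with an estimated correlation, and bile duct genes (16 of 17 higher, median 1.98, camera adjusted p = 7.83e-06) had adjusted p = 0.509 with an estimated correlation. The mucosal glycoprotein gene Dmbt1 (13.91 ± 2.69) and Adgrg7 (10.70 ± 1.99) had edgeR adjusted p = 0.32. EdgeR called 0 genes (722 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 49, and edgeR 67 without metformin replicate 1 and 7 without replicate 4. The bile duct list lost its call without metformin replicate 3 (camera adjusted p = 0.527). Adjusted over the list alone, 6 tumour markers and 3 bile duct genes (higher) and 4 neutrophil genes (lower) passed.

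A main effect of oxymetholone, over mutants with and without metformin, was added after the data were examined. The integrated stress response list lay higher in 18 of 19 (median log2 difference 0.54, camera adjusted p = 8.82e-07). It passed also with an estimated correlation (adjusted p = 0.00205) and with fry (0.00372). Ddit3 (1.0 ± 0.21), Psat1 (1.36 ± 0.40) and Atf3 (1.61 ± 0.55) led it (edgeR adjusted p = 0.131, 0.48 and 0.644). Psat1 had 23.3 CPM in combination replicate 3, at most 5.90 elsewhere. Interferon response genes lay higher in 28 of 28 (median 0.81, camera adjusted p = 7.09e-14, and 0.546 with an estimated correlation). EdgeR called 20 genes (14 higher, 6 lower), which included Paqr8 (2.97 ± 0.27, edgeR adjusted p = 6.74e-05), Lncbate1 (5.64 ± 0.55, edgeR adjusted p = 7.91e-05), Tmem62 (−1.99 ± 0.20, edgeR adjusted p = 7.91e-05), Cyp2a4 (3.99 ± 0.74, edgeR adjusted p = 0.0444) and the X-linked gene Xlr4c (4.64 ± 0.80, edgeR adjusted p = 0.0299). The count fell to between 9 and 13 without any untreated mutant library, metformin replicate 1, oxymetholone replicate 1, 2 or 5 or combination replicate 1. Xlr4c lost its call without any untreated mutant or metformin library, oxymetholone replicate 1 or 5 or combination replicate 1 (0.0599 to 0.151), and Cyp2a4 without any 1 of the 14 libraries but metformin replicate 4, oxymetholone replicate 4 and combination replicate 1 (0.0566 to 0.196). Over all 18 libraries, 13 genes were higher and 4 lower in every one of the 8 libraries with oxymetholone than in each of the 10 without, where 0.368 per direction are expected. A main effect of metformin gave 0 genes by edgeR (994 at an unadjusted p under 0.05), 0 by limma-voom and 28 by DESeq2, while cholesterol synthesis genes lay lower in 25 of 25 (median −0.63, camera adjusted p = 3.73e-15), with adjusted p = 0.651 with an estimated correlation. Adjusted over the list alone, 2 stress response genes and 7 interferon response genes passed (higher) for oxymetholone, and 0 cholesterol synthesis genes for metformin.

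**Figure D2:**
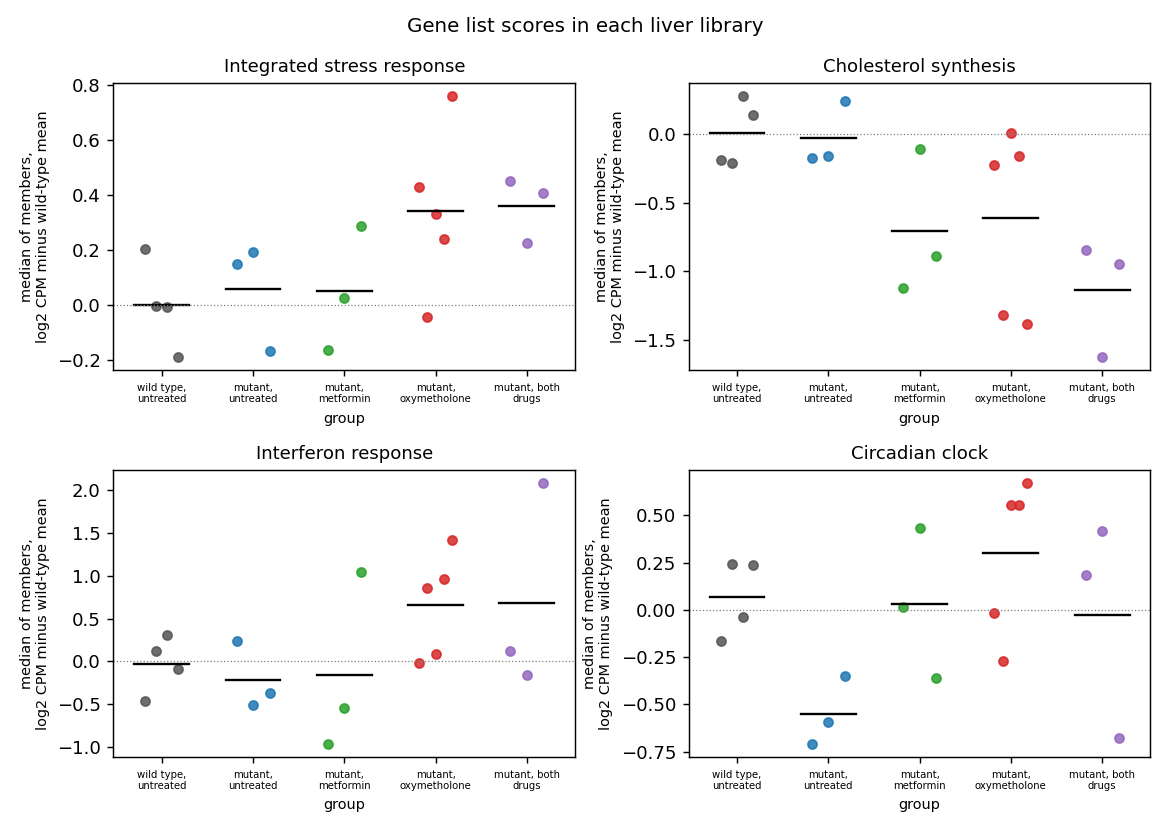
Scores of 4 gene lists per library, in log2 units relative to the wild-type mean (median over the list's genes), with a point per library and a line at the group mean. Cholesterol synthesis genes lay below the wild-type mean in the combination mutants, where the median log2 difference from wild type was −1.0.

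Effects of the drugs were compared with each other through their log2 differences across 16115 genes, which are not independent replicates. Oxymetholone and the combination correlated at r = 0.689, and groups without any effect that share the 3 untreated mutants gave 0.561. The covariance exceeded the simulated one by 0.0402, and with the untreated libraries split 1 against 2 the mean correlation was 0.192, from −0.0677 to 0.366 over the 6 splits. Wif1, Paqr8 and Lncbate1 were called higher in both, and the 2 comparisons share their untreated libraries. Metformin and the combination correlated at 0.583 (simulated 0.503, covariance difference 0.026, split 0.147, from −0.104 to 0.29), and metformin and oxymetholone at 0.562 (simulated 0.563, covariance difference 0.00883, split 0.112, from −0.12 to 0.28). Part of each excess may come from the shared controls. Whether a drug moved genes back toward wild type was tested with split controls, where the genotype effect correlated with the effect of metformin at a mean of −0.0476 (−0.218 to 0.212 over the 6 splits), of oxymetholone at −0.0302 (−0.192 to 0.228) and of the combination at 0.0803 (−0.0891 to 0.287). Unsplit values were −0.538, −0.557 and −0.352, against −0.538, −0.601 and −0.537 in simulations without any effect. For oxymetholone, 2 estimates that share no library (with and without metformin) correlated at 0.118 (permutation p = 0.312), and for metformin at 0.0723 (permutation p = 0.409), over 1000 permutations each.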

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

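The tests of read carry-over, of random positions and of the smallest p over all lists, the clock score as a covariate and the 2 main effects were chosen only after the results were seen. Of 310 groups of values checked for a library far from the others of its group, 22 had one (7.1%, 10 in wild type and 12 with oxymetholone), while chance marks about 1 in 20 groups. Groups of 3 were not checked. In wild type, replicate 2 lay above the others in the bile duct score (1.61), the p53 target score (0.473), and the log2 CPM of H19 (2.90) and Epcam (2.74). Replicate 1 lay low in Nkd1 (1.76) and Aldh1b1 (5.21) and high in Rps19 (8.40), replicate 3 high in Sult3a2 (0.16), and replicate 4 high in Catsperd (2.36) and low in Phgdh (−0.70). With oxymetholone, replicate 4 lay high in the percent of counts in the 10 strongest genes (29.0) and the acute-phase score (2.12). Replicate 3 lay high in the percent of mitochondrial counts (8.19), the pericentral score (−0.0933) and Serpina1e (13.82), replicate 2 high in Cenpf (0.16) and Mcmdc2 (−3.15) and low in the steroid response score (−0.181), replicate 1 high in Synpo2 (0.21) and Adgrg7 (−3.12) and low in Gm20442 (−3.73), and replicate 5 high in Cyp2c39 (5.99).

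Camera with the preset correlation called 11 lists in the interaction of the drugs, of which 4 were reported above: male-biased genes (adjusted p = 4.09e-06), female-biased genes (0.00285), acute-phase genes (0.000116) and ribosomal protein genes (1.15e-09). All 4 had adjusted p = 0.925 with an estimated correlation, and as many lists came from most other splits, so these differences are not told from chance.

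Genes called were compared with other splits of the same libraries, given as the number of splits with as many calls, the real one included, and the highest count of any other split. For oxymetholone 2 of 56 splits reached its 7 genes (highest other 20). For oxymetholone mutants against wild type 1 of 100 reached the 16 (highest other 1), and for combination mutants against wild type 1 of 35 reached the 4 (highest other 0). Each of these 3 shares lies under 0.05, without adjustment over the comparisons, and the 3 comparisons share libraries. They argue against chance for each count taken alone, least for oxymetholone, where another split called more genes. Chance cannot be excluded for oxymetholone against metformin (9 genes, 4 of 56 splits, highest other 2123) or the oxymetholone main effect (20 genes, 5 of 100, highest other 941). Where edgeR called 0 genes every split reaches that count, so these splits say nothing about chance. It was 35 of 35 for genotype (highest other 0, 416 at an unadjusted p under 0.05), 56 of 56 for combination against oxymetholone (88, 461), 100 of 100 for the interaction (2233, 483), 35 of 35 for metformin mutants against wild type (15, 722) and 100 of 100 for the metformin main effect (5247, 994). DESeq2 called 0, 1, 3, 49 and 28 genes in these 5 and limma-voom 0 in each. The same holds for metformin (0 genes by edgeR and limma-voom, 11 by DESeq2, 10 of 10 splits, highest other 0, 914 at an unadjusted p under 0.05) and combination against metformin (0 genes by edgeR, 10 by DESeq2 and 3 by limma-voom, 10 of 10, highest other 358, 552). The combination (3 genes, 1 of 10, highest other 0) has too few splits for a share under 0.05. Splits that call several times the real count point to a structure of the samples. The split with 2123 genes put metformin replicates 3 and 4 with oxymetholone replicates 3 to 5, and the split with 20 genes put oxymetholone replicates 1 and 2 with the untreated mutants.

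Lists called by camera with the preset correlation were not told from chance in any comparison with enough splits. As many lists came from 23 of 35 splits for genotype (12 lists, highest other 28), 19 of 56 for oxymetholone (15, 26), 44 of 56 for combination against oxymetholone (11, 24), 38 of 56 for oxymetholone against metformin (12, 24) and 77 of 100 for the interaction (11, 29). Against wild type it was 12 of 35 for metformin (17, 23), 73 of 100 for oxymetholone (10, 22) and 20 of 35 for the combination (19, 28), and for the main effects 63 of 100 for oxymetholone (13, 25) and 39 of 100 for metformin (17, 28). Metformin (15 lists, 5 of 10 splits, highest other 23), the combination (18, 7 of 10, 28) and combination against metformin (15, 6 of 10, 25) have too few splits for a share under 0.05. The integrated stress response list with an estimated correlation stood apart in the oxymetholone main effect: p was 5.69e-05 before adjustment, 1 of 100 splits gave a p as small, and the smallest of the others was 0.00837. That list was picked because it passed, so this alone decides nothing. Over all 36 lists 1 of 100 splits had some list with a p as small, with 0.000621 as the smallest in the others. That allows for the choice among lists and not for the choice of this comparison after the results were seen, so whether chance can be excluded stays open. As for the number of lists that passed, 4 of 100 splits had as many as the real 1 and the highest other had 2.

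A first pattern was the set of 7 genes called with oxymetholone, which might reflect another time of day at collection, because clock genes differed as well (mean clock score 2.39 with oxymetholone and −3.45 in untreated mutants). The slope of each gene on the clock score over the 10 libraries without oxymetholone gave a median share of 0.173 of the log2 difference, 0.124 to 0.186 with 1 library left out. Shares were 0.354 at most (Wif1) and negative for Rab38 (−0.355) and Ubr1 (−0.118). That argues against time of day as the whole cause. With the clock score as a covariate edgeR called 6 genes, 4 of them among the 7, and Rab38 (log2 difference 2.32 ± 0.40 before and 2.64 ± 0.49 after), Ubr1 (−1.92 ± 0.26 and −1.73 ± 0.32) and Mcmdc2 (−6.40 ± 1.03 and −5.52 ± 1.29) lost their calls at edgeR adjusted p = 0.083, 0.083 and 0.34, mainly because the error grew. A part of the difference in Ubr1 and Mcmdc2, which the covariate shrank, and a drug effect on the clock, stay open.

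A second pattern was a low level of Dmbt1 and Adgrg7, which metformin replicate 3 expressed at 3764 and 214 CPM, in some other libraries and not in others. Dmbt1 lay at 5.33 to 8.69 CPM in the 3 untreated mutants, 6.74 and 4.35 CPM in the other metformin libraries, 7.85 CPM in combination replicate 3 and 1.16 CPM in oxymetholone replicate 1, against 0.214 CPM or less elsewhere, and the ratio of Dmbt1 to Adgrg7 reads was 15.6 over the 17 other libraries (1137 to 73 reads, exact 95% interval 12.3 to 20) and 17.6 in that library. Carry-over of reads from metformin replicate 3 would give this, but the test on 39 other genes high there was open: their median slope on the Dmbt1 share was 4.83 (quartiles 1.70 and 19.5), and in most of them the level in other libraries (0.687 to 4.90% of that library's, as medians over the 39 genes per library) would hide a Dmbt1 share of at most 0.231%. The 3 with a lower median level were mixed: Slc26a3 (155 CPM in that library, median 0.0869 CPM in the others) had a slope of 0.866 and a correlation with Dmbt1 of 0.874, Spink4 (31.4 and 0 CPM) 1.94 and 0.77, and Olfm4 (133 and 0.203 CPM) 0.146 and 0.368, where carry-over predicts a slope of 1. Bile duct or gut cells of the animals themselves were tested with 4 bile duct markers, all of which liver tissue also expresses, whose median correlation with Dmbt1 was 0.198 (Krt19 0.499, Krt7 0.208, Epcam 0.188, Spp1 0.0852), under a bound of 0.2 set before but by less than their spread, a condition added after the value was seen. Both stay open and cannot be told apart, and if reads were carried over, the libraries with them could have been sequenced together and most oxymetholone and wild-type libraries apart, a batch that the labels do not give.

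The last pattern was that genes called in the oxymetholone main effect neighbour each other on the chromosomes. Of 20 called genes 18 could be placed, and 5 lay within 2 places of another (Mcmdc2 with Tcf24, Tcf24 with Ppp1r42, Ubr1 with Tmem62), while random positions gave at most 4 in 10000 sets (permutation p = 0.0001, the smallest they can give). With 1 library left out, 2 to 5 genes did so (permutation p = 0.0001 to 0.0333). Ubr1 and Tmem62 stayed called without any 1 library, while Tcf24 and Ppp1r42 lost their calls without 13 of 14 and Mcmdc2 without 8 of 14. The run of 3 genes rests on calls that do not hold. The other pair was seen before the test was chosen, so random positions stay open. Reads shared between overlapping genes were argued against by 0 of the 3 pairs overlapping in the reference. None of the 9 flanking genes had an unadjusted edgeR p under 0.05, so a longer stretch of changed expression was not seen. A shared enhancer, or a difference in litter or chromosome segment between the groups, may underlie it and was not tested, since the labels name neither.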

How the results depend on the processing

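Leaving out metformin replicate 3 together with combination replicate 3, the 3 recovered factors, the surrogate variables, the clock score, the 2 main effects and the thinning of reads were chosen only after the results were seen. In the oxymetholone comparison Paqr8, Wif1, Lncbate1 and Tmem62 passed under every tool, filter, scaling, covariate and left-out library. Among the gene calls, those of DESeq2's size factors were the same as the main ones in every comparison, and moved the median of all genes by at most 0.0372 (log2). Dropping the filter was void, because no gene had been removed. No paired analysis was possible because the labels carry no replicate numbers and those used here follow the record order. Depth limits weak genes: with reads thinned to 50 and 25%, the filter left 14528 and 12922 genes. Among the genes left, standard errors for oxymetholone rose by a median of 1.12 and 1.26 times in the weakest 25% of genes, against 1.002 and 1.005 in the strongest. Calls for oxymetholone fell from 7 to 5 and 5, and those against wild type went from 16 to 17 and 10. With 1 untreated or metformin library fewer, 2 remain in that group, and the spread comes from the pooled fit. At an unadjusted p under 0.05 limma-voom had 4080, 2208, 3310 and 1933 genes for genotype, metformin, oxymetholone and the combination, where edgeR had 416, 914, 773 and 880. The cause was not tested for any change below, except where fewer genes or libraries were compared.

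DESeq2 called 11 genes for metformin, 78 for oxymetholone, 43 for the combination, 1 and 10 for combination against oxymetholone and metformin, 107 for oxymetholone against metformin, 3 for the interaction, 49, 89 and 70 for metformin, oxymetholone and combination mutants against wild type, and 79 and 28 for the main effects of oxymetholone and metformin. It kept 8 and limma-voom 6 of the 9 calls of oxymetholone against metformin, and DESeq2 kept every edgeR call of the other comparisons. Limma-voom called 14 for oxymetholone (7 of 7 kept), 16 for the combination (3 of 3), 3 for combination against metformin, and 43 and 35 for oxymetholone and combination mutants against wild type (16 of 16 and 4 of 4). Fits of the compared groups alone called 0 for the combination, 0 for oxymetholone against metformin, and 25 and 1 for oxymetholone and combination mutants against wild type (15 of 16 and 1 of 4 kept), with fewer libraries to estimate the spread. Of the 20 calls of the oxymetholone main effect, limma-voom kept 15 and a mean CPM of at least 1 kept 12, with fewer genes tested.

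Without both metformin replicate 3 and combination replicate 3, edgeR called 15 genes for oxymetholone and 5 for the combination, and camera called 8 lists instead of 19 for combination mutants against wild type. The 3 recovered factors gave 2 genes for genotype, 60 for oxymetholone, 5 for the combination, 5 for combination against metformin, 95 and 7 for oxymetholone and combination mutants against wild type and 75 for the main effect of oxymetholone. Surrogate variables gave 1 for genotype, 54 for oxymetholone, 6 for the combination, 7 for combination against metformin, 97 for oxymetholone mutants against wild type and 75 for the main effect of oxymetholone. With either covariate set all 7 oxymetholone calls were kept.

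With 1 library left out, counts ran from 0 to 0 genes for genotype, metformin, combination against oxymetholone, the interaction and the metformin main effect. They ran from 4 to 7 for oxymetholone (4 without untreated mutant replicate 4), 0 to 3 for the combination (0 without untreated mutant replicate 2 or 4, 2 without replicate 3), 0 to 2 for combination against metformin (2 without combination replicate 3) and 5 to 153 for oxymetholone against metformin (5, 57 and 153 without metformin replicate 3, 4 and 1). Against wild type they ran from 0 to 67 for metformin (7 and 67 without metformin replicates 4 and 1), 9 to 17 for oxymetholone (9 without wild-type replicate 4) and 3 to 6 for the combination, and for the oxymetholone main effect from 9 to 18 (9 without untreated mutant replicate 4 or metformin replicate 1).

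Few list calls passed the 2 other tests. With an estimated correlation, and with fry, 0 lists were called for genotype, metformin, oxymetholone, the combination, combination against oxymetholone, the interaction, metformin and combination mutants against wild type and the metformin main effect. The estimated correlation left 1, the integrated stress response, for combination against metformin, oxymetholone against metformin, oxymetholone mutants against wild type and the oxymetholone main effect, where fry left 0, 0, 0 and 1. With 1 library left out the lists called ran from 2 to 16 for genotype (2 without untreated mutant replicate 2), 8 to 19 for oxymetholone (8 without that library), 7 to 19 for combination against oxymetholone, 6 to 16 for the interaction, 9 to 17 and 8 to 25 for oxymetholone and combination mutants against wild type (8 without combination replicate 3).

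Some named genes without a call at first changed direction. Limma-voom reversed Cd14 for genotype (−0.44) and Cyp3a16 for the combination against oxymetholone (−0.72) and wild type (−0.0208). Without both replicates 3, Krt19 was at −0.88 and Acta2 at −0.31 for metformin, Krt19 at 0.0553 for oxymetholone against metformin and −0.0638 for metformin against wild type, and Cyp3a16 at −2.06, −0.42 and −1.21 for the combination against oxymetholone, metformin and wild type. With the 3 recovered factors the metformin differences of Muc1, Krt19, Des, Acta2 and Epcam were −0.52, −2.69, −0.39, −1.90 and −0.47, and with surrogate variables −0.52, −2.62, −0.35, −1.87 and −0.49. These 2 sets also gave Krt19 0.85 and 0.33 for oxymetholone against metformin and Cyp3a16 −0.26 and −0.32 for the combination against wild type, the factors gave Krt19 −0.17 for metformin against wild type, and the surrogate variables gave Serpina1e 0.28 for the interaction. The clock score turned Krt19 for genotype (−0.0171).

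With 1 library left out, Mup22 ran from −0.13 to 5.49 and Cd14 from −1.35 to 3.10 for genotype (lowest without untreated mutant replicates 3 and 2), Krt19 from −0.90 to 5.95 and Acta2 from −0.32 to 4.87 for metformin, Krt19 from −0.11 to 7.01 for metformin against wild type and from −6.66 to 0.0729 for oxymetholone against metformin, and Muc1 from −7.30 to 0.25 for combination against metformin, all 5 turned by metformin replicate 3. Without metformin replicate 1 Krt19 passed for oxymetholone against metformin (edgeR adjusted p = 0.0166, up to 0.995 over its alternatives) and for metformin against wild type (0.0474, up to 1). Cyp3a16 ran from −1.22 to 6.57 and from −2.05 to 5.73 for the combination against wild type and oxymetholone (lowest without combination replicate 3), and Serpina1e from −5.77 to 0.52 for the interaction (highest without oxymetholone replicate 3).

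Lists whose direction turned were, with camera's adjusted p over the left-out libraries, the Fanconi pathway (0.65 to 0.995) and p53 targets (0.108 to 0.938, and 0.975 with fry) for genotype, gluconeogenesis for metformin (0.216 to 0.813), and iron (0.229 to 0.976), growth hormone (0.4998 to 0.922), female-biased (0.263 to 0.87), p53 (0.145 to 0.977) and Fanconi genes (0.623 to 0.957) for oxymetholone, none of which passed. Female-biased genes ran from 0.00067 to 0.904 for the combination (turned without combination replicate 3), male-biased genes from 4.2e-10 to 0.118 for combination against oxymetholone (turned without the same library, and at 0.12 without both replicates 3), and bile duct genes from 1.74e-07 to 0.574 for combination against metformin (turned without metformin replicate 3).

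Drug effects correlated at 0.112 (metformin and oxymetholone), 0.147 (metformin and combination) and 0.192 (oxymetholone and combination) with split untreated mutants, against 0.562, 0.583 and 0.689 unsplit, where the contrasts share those libraries. The correlation of the genotype effect with the effect of metformin was −0.538 unsplit, with oxymetholone −0.557 and with the combination −0.352. With split libraries its mean was −0.0476, −0.0302 and 0.0803 over all genes, with both signs among the 6 splits of each, and −0.236, −0.161 and −0.274 over the 38 genes with a genotype p under 0.01. That p uses all 3 untreated libraries, which by itself can lower these 3 values, so they say nothing about a reversal.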

Other observations

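The separation of libraries with and without oxymetholone was examined only after the results were seen. Each of the 8 libraries with oxymetholone lay above each of the 10 without it for 13 genes, and below for 4, where 0.368 are expected in each direction. Of 999 shuffles of the libraries 3 gave as many genes, with 48 at most. Among them were Smim1 (17.2 against 2.85 CPM), Corin (0.688 against 0.303 CPM), the chaperone gene Hspa8 (606 against 434 CPM) and Ptprk, which was lower (28.1 against 39.8 CPM), chosen here after their values were seen because no list holds them.

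Single libraries carried large values of a few genes. Metformin replicate 3 held 237 CPM of Krt19 and 3764 CPM of Dmbt1. Combination replicate 3 held 46.1 CPM of Cyp3a16 and had a TMM factor of 1.31. Oxymetholone replicate 3 held 14474 CPM of Serpina1e, against at most 67.0 CPM in the other 4 libraries of its group.

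In the deposited results of the authors, 0 genes are called for genotype, metformin, the combination, combination against metformin, combination against oxymetholone and the interaction, by a test not given in the sources used here, with 904, 597, 1380, 798, 828 and 585 at an unadjusted p under 0.05. Their log2 differences correlated with those of edgeR at 0.796 for genotype, 0.864 for oxymetholone, 0.640 for the combination and 0.459 for metformin.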
